A study of Arabidopsis thaliana with 32 samples.

How the data were processed

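Gene expression was measured in whole seedlings of Arabidopsis thaliana with 32 single-colour (Cy3) NimbleGen arrays, 4 for each combination of genotype (Columbia wild type or sahh1) and age (1, 4, 7 or 10 days). Total RNA was extracted with the RNeasy Plant Mini Kit. Per the labels the authors normalized the arrays with RMA, with no version given. The deposited table holds 1 normalized intensity per locus and array on a linear scale, with each locus once. Log2 was taken before any test. No probe-level data were used, so background and probe effects could not be examined.

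Loci were matched to the reference annotation by locus tag: 29996 were found, 10357 have a symbol and 3827 are pseudogenes. Pseudogene is the biotype given there. Transposable element genes were to form a list where the reference marks them, and no such list was formed. Loci of that kind may therefore be counted among the pseudogenes. Symbols in the text are those of the reference, except SAHH1 for the locus listed as HOG1. The genome build of the table is not stated, so no coordinates are given.

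The groups, the tests, the 23 gene lists and most alternatives were fixed before the data were examined. 2 choices differ from that plan. The plan counted 32 arrays as replicates. In all 8 groups arrays 1 and 2, and arrays 3 and 4, were closer to each other than to the other pair: at days 1, 7 and 10 the SD of the difference across 18621 bright loci was 0.126 to 0.153 within pairs and 0.208 to 0.383 between pairs, and at day 4 it was 0.218 to 0.448 within and 0.336 to 0.801 between. The labels do not say what the pairs are. Before any test of genotype, each pair was therefore averaged into 1 sample, leaving 16 samples and n = 2 per group, and counts with 32 arrays are given beside those of the samples. The second concerns age: array medians differ between ages and hardly within them, so an effect of age cannot be told apart from normalization or hybridisation by age. Comparisons between ages and the interaction were therefore made after quantile normalization over all 32 arrays (limma), while comparisons of genotype used the values as deposited.

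Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 8 groups, 8 residual degrees of freedom and an empirical Bayes prior of 3.16 degrees of freedom for genotype and 2.54 between ages. The contrasts were sahh1 against wild type at each age and on the mean of the ages, successive ages within each genotype, and the change of the genotype difference between ages, with an F test over all ages. P values were adjusted by Benjamini-Hochberg over all loci of a contrast and called under 0.05. No filter on level was applied. Percentages of wild type for SAHH1 and SAHH2 carry 95% intervals of the limma fit.

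The 23 lists were written from general knowledge and are: methyl cycle and methionine, other SAM-using metabolism, DNA methylation and silencing machinery, genes silenced by DNA methylation, root hair, root epidermal patterning, root meristem, stele and endodermis markers, photosynthesis, seed storage and maturation, storage oil mobilisation and germination, mitotic cell cycle and DNA replication, cytokinin, auxin, phenylpropanoid and lignin, flavonoid and anthocyanin, glucosinolate synthesis, salicylic acid and pathogen defence, jasmonate and ethylene defence, iron deficiency, phosphate starvation, abscisic acid and cold, heat shock, and stable reference genes for the scaling check. Of 444 entries 443 were used. The entries NMT2, EXT13 and CRU2 were moved from the planned locus to the one the reference gives for the symbol, and that of CRU2 was already in its list. They were tested with camera at a preset correlation of 0.01 between genes, with a correlation estimated from the data, and with fry, each adjusted over the 92 combinations of list and age. Members were also adjusted over the list alone. The share of pseudogenes among called genes was tested with Fisher's exact test, a test chosen after the data were seen. It counts loci as independent, although adjacent loci were often called together. Its intervals do not hold the spread between samples.

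The fit was tested on simulated data in which each gene had a single spread, the average over the 8 groups, and genes varied independently. At day 1 it recovered 1 of 50 genes changed by 0.5 on the log2 scale, 25 of 50 changed by 1, 46 of 50 changed by 2 and 50 of 50 changed by 4, none in the wrong direction. It made 12 false calls beside 122 true ones, which is more than the 5% the threshold aims at, and 0 calls at ages left unchanged. The larger spread of the real sahh1 samples of day 4 was not simulated. The simulation therefore does not tell how many calls at day 4 are false. Changes under 2-fold are thus mostly missed with 2 samples per group.

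The alternatives fixed beforehand were cyclic loess, scaling to the reference genes, leaving out the dimmest 25% of loci (7596), array weights, an intensity trend with a robust prior, only the groups compared, a replicate block, leaving out each array, an adjusted p under 0.01 and a 2-fold minimum. Keeping 1 row per locus had nothing to change. The planned count of 32 separate arrays was kept as a further alternative. Chosen after the data were examined were 32 arrays with the sample as a random block, quantile normalization for genotype, values as deposited between ages, a crossed replicate block at days 1 and 10, and leaving out each of the 16 samples. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.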

Results

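Whole seedlings of Arabidopsis thaliana, either Columbia wild type or sahh1, were measured at the ages of 1, 4, 7 and 10 days. There are 32 arrays, 4 for each of the 8 combinations of genotype and age. The sahh1 mutant is deficient in S-adenosylhomocysteine hydrolase 1, an enzyme that removes S-adenosylhomocysteine, the by-product of methylation reactions that draw on S-adenosylmethionine. The comparisons ask how gene activity in the mutant differs from wild type at each seedling age. Of the loci on the arrays 29996 have an annotation in the reference and 10357 a symbol. Arrays 1 and 2 of every group were closer to each other than to arrays 3 and 4, so each pair was averaged into 1 sample and n is 2 samples per group throughout. The labels do not say so and the plan counted 32 arrays, so counts with 32 arrays are given beside. Median intensity was 995 to 1054 per array at day 1, 449 to 493 at day 4, 1793 to 1945 at day 7 and 956 to 982 at day 10. Levels were therefore compared between genotypes within an age as deposited and between ages only after quantile normalization. The number of samples limits the precision of every value below. Differences are sahh1 minus wild type on the log2 scale with the standard error (SE) of the limma fit. Adjusted p values are Benjamini-Hochberg values from limma over all loci, and a gene is called at an adjusted p under 0.05. For lists, the members called when p is adjusted over the list alone are given too.

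The SAHH1 transcript (AT4G13940, listed as HOG1 in the reference) was called lower in sahh1 than in wild type at days 1 and 4. Its level in sahh1 was 41.6% of wild type at day 1 (95% interval 29.1 to 59.4, adjusted p = 0.0117) and 34.5% at day 4 (24.2 to 49.3, adjusted p = 0.0144). It was 71.7% at day 7 (50.2 to 102, adjusted p = 0.723) and 58.8% at day 10 (41.2 to 83.9, adjusted p = 0.276). Neither was called after adjustment over all loci, although the interval of day 10 lies wholly below the wild-type level. All 4 sahh1 arrays lay below all 4 wild-type arrays at every age. The permutation p of 0.0286 is the smallest that 4 against 4 arrays can give, but the arrays are 2 pairs and 2 samples against 2 cannot give an exact p under 0.333. The paralogue SAHH2 (AT3G23810) stood at 89.2%, 100.1%, 112% and 106% of wild type at days 1, 4, 7 and 10, and was not called (lowest adjusted p 0.997). The SAHH1 call at day 1 was lost without sahh1 sample 1 (adjusted p = 0.108), without sahh1 sample 2 (0.0634), without wild-type sample 1 (0.0735) and without wild-type sample 2 (0.107). At day 4 it was lost without wild-type sample 1 (0.0710) or 2 (0.106). It was also lost at day 4 with array weights (0.103) and with the groups compared alone (0.542). At day 10 the difference was called without either sahh1 day 4 sample (0.00673), with array weights (0.0226) and with arrays in place of samples (0.00124).

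**Figure D1:**
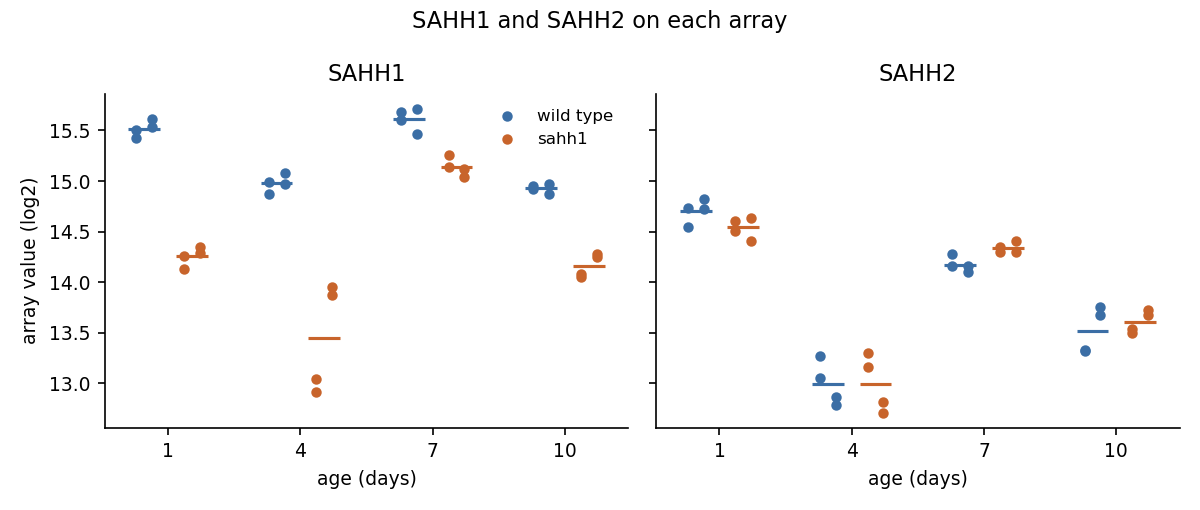
Log2 values of SAHH1 (left) and SAHH2 (right) on each of the 32 arrays by age in days, wild type in blue and sahh1 in orange, with a horizontal line at each group mean and the 2 arrays of a sample drawn above one another. The scale differs between ages, so genotypes are to be compared within an age: every sahh1 array lies below every wild-type array for SAHH1 at all 4 ages, and the SAHH1 values of the first sahh1 sample at day 4 average 12.98.

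At day 1, loci with little signal in wild type rose in sahh1 seedlings. Among them were the pseudogene loci AT3G44215 (log2 difference 6.59 ± 0.54), AT2G06370 (6.40 ± 0.30) and AT2G04770 (6.20 ± 0.34), and the protein-coding locus AT3G54730 (5.77 ± 0.30, adjusted p = 7.30e-07). Where the wild-type level is near background, here and at the other ages, the size of a rise depends on that background and is not exact. In all, 746 genes were called, 656 higher and 90 lower in sahh1, of which 608 and 53 differed at least 2-fold. Of the 651 risers with an annotation, 534 (82.0%) were pseudogenes, against 3827 of all 29996 annotated loci (12.8%). Pseudogene is the biotype of the reference, here and below, and may include transposable element genes, which were not separated. The odds ratio was 36.1 (95% interval 29.4 to 44.6, Fisher's exact test), and among loci below the median level the odds ratio was 17.7 (14.2 to 22.2). These intervals, here and below, count loci as independent and do not show the spread between samples. Of the 90 genes lower at day 1, 12 were pseudogenes (odds ratio 1.05, 0.521 to 1.95, and 0.660, 0.310 to 1.29, below the median level). The median over the risen pseudogenes of the mean log2 level was 4.37 in wild type and 6.73 in sahh1, where the lower quartile of all loci was 4.81. Among genes known to be silenced by DNA methylation, 3 of 14 rose: AT4G08680 (2.93 ± 0.41, adjusted p = 0.00140), QQS (AT3G30720, a regulator of starch content, 2.28 ± 0.37, 0.00409) and AT2G12210 (1.59 ± 0.18, 3.20e-04). The call of QQS was lost without wild-type sample 2 (adjusted p = 0.0616) or sahh1 sample 2 (0.0577), and that of the whole list without sahh1 sample 2 (0.0687) and with the groups compared alone (0.121). That list rose by camera (adjusted p = 0.0186 and adjusted p = 0.319 with an estimated correlation, 0.0508 by fry), with a median of 0.05 and a mean of 0.49.

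Genes that fell at day 1 included IBM1 (AT3G07610, a histone H3K9 demethylase; -1.19 ± 0.19, adjusted p = 0.00408), the seed storage protein gene CRU2 (AT1G03880; -1.73 ± 0.26, 0.00246) and AT1G47400 (-2.16 ± 0.26, 4.34e-04), the largest fall. The iron deficiency list fell as a set (median -0.21, 15 members, adjusted p = 5.59e-04 and adjusted p = 0.162 with an estimated correlation, 0.0352 by fry). In it 2 members were called, or 4 adjusted over the list alone. The 2 were the transcription factor gene BHLH100 (AT2G41240; -1.53 ± 0.34, 0.0402) and the transporter gene OPT3 (AT4G16370; -0.65 ± 0.12, 0.0137). The mitotic cell cycle and DNA replication list fell (median -0.38, 29 of 30 members negative, adjusted p = 7.77e-09 and adjusted p = 0.403 with an estimated correlation, 0.0856 by fry). In it CDC20.1 (AT4G33270) was called at -0.72 ± 0.16 (adjusted p = 0.0389) and 9 members were called adjusted over the list alone. The flavonoid and anthocyanin list fell (median -0.41, adjusted p = 1.79e-04 and adjusted p = 0.438 with an estimated correlation, 0.227 by fry). Glucosinolate synthesis fell too (median -0.23, adjusted p = 0.00875 and adjusted p = 0.768 with an estimated correlation, 0.578 by fry). No member was called in either list, and 1 and 2 members were called adjusted over the list alone. Seed storage and maturation was not called as a set (median -0.09, adjusted p = 0.111), although 3 of its 26 members fell. The call of IBM1 was lost without wild-type sample 2 (0.0551), that of glucosinolate synthesis without wild-type sample 1 (0.0512) and that of OPT3 without sahh1 sample 1 (0.153), sahh1 sample 2 (0.0713), wild-type sample 1 (0.0629) or wild-type sample 2 (0.156). That of BHLH100 was lost without sahh1 sample 1 (0.322), sahh1 sample 2 (0.110), wild-type sample 1 (0.258), wild-type sample 2 (0.193), either sahh1 day 7 sample (0.0549), either sahh1 day 10 sample (0.0629) or either wild-type day 10 sample (0.0565). That of CDC20.1 was lost without sahh1 sample 1 (0.176), sahh1 sample 2 (0.236), wild-type sample 1 (0.477), either wild-type day 4 sample (0.0642), either sahh1 day 7 sample (0.0622), either wild-type day 7 sample (0.0577) or either wild-type day 10 sample (0.0562). With a replicate block the calls of OPT3 (0.0840), BHLH100 (0.119) and CDC20.1 (0.119) were lost too. After quantile normalization over all arrays those of CRU2 (0.209), BHLH100 (0.103) and CDC20.1 (0.0902) were lost. With the groups compared alone those of QQS (0.0781), AT2G12210 (0.0534), OPT3 (0.0947) and CDC20.1 (0.191) were lost. After scaling to the reference genes BHLH100 (0.0665) and CDC20.1 (0.0523) were lost, and BHLH100 with the dimmest loci left out (0.0568). The number of genes called at day 1 was 424 with the dimmest 25% of loci left out, 446 after quantile normalization over all arrays, 1446 with array weights and 1736 with 32 arrays in place of 16 samples.

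**Figure D2:**
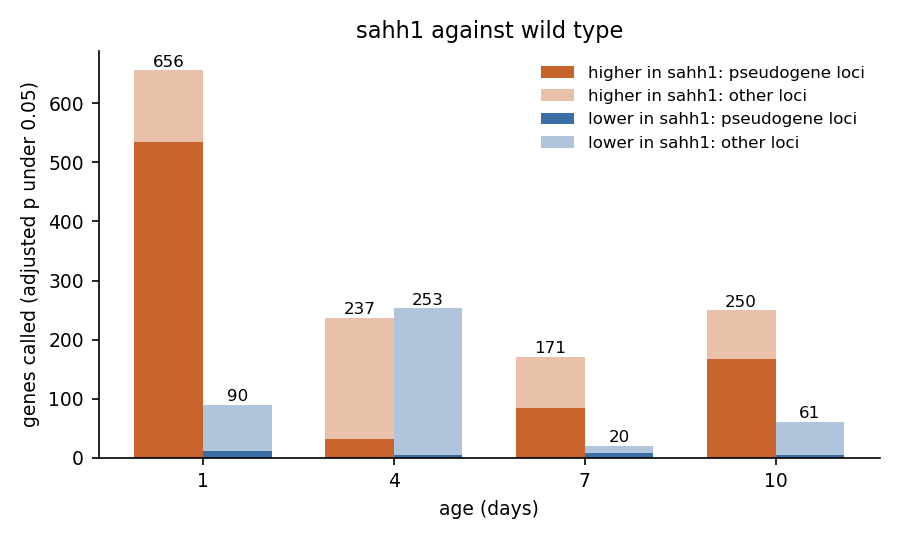
Number of genes called at each age in days, higher (orange) or lower (blue) in sahh1, with 2 samples per group; the dark part of each bar counts pseudogene loci, 534 of the 656 risers at day 1. The bars start at 0 and the number above each is its total.

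At day 4, members of the root hair and heat shock lists were among the genes lower in sahh1, and 3 methylation-silenced genes were among the higher ones. In the root hair list 8 of 42 members fell (30 adjusted over the list alone). Among them were RHS14 (AT4G22080; -2.07 ± 0.37, adjusted p = 0.0244), MRH6 (AT2G03720; -1.94 ± 0.33, 0.0210), RHS16 (AT4G29180; -1.77 ± 0.33, 0.0300) and the expansin gene EXPA7 (AT1G12560; -1.44 ± 0.28, 0.0329). Its median was -1.10 (adjusted p = 2.04e-20 and adjusted p = 0.264 with an estimated correlation, 0.0352 by fry). In the heat shock list 3 of 9 members fell (6 adjusted over the list alone). They were HSP21 (AT4G27670; -1.98 ± 0.26, 0.00579), HSP23.6-MITO (AT4G25200; -1.68 ± 0.25, 0.0135) and HSP17.6II (AT5G12020; -1.59 ± 0.23, 0.0118). The list median was -1.36 (adjusted p = 4.79e-08 and adjusted p = 0.162 with an estimated correlation, 0.00731 by fry). The aquaporin genes TIP2;3 (AT5G47450; -2.73 ± 0.32, 0.00303) and PIP2;4 (AT5G60660; -1.84 ± 0.22, 0.00362) were the 2 of 18 root meristem, stele and endodermis markers that fell. That list fell as a set (median -0.36, adjusted p = 0.0186 and adjusted p = 0.727 with an estimated correlation, 0.346 by fry). Risers included QQS (3.74 ± 0.37, 7.50e-04), SDC (AT2G17690, an F-box gene; 3.25 ± 0.55, 0.0210), FWA (AT4G25530, a homeodomain gene; 1.74 ± 0.27, 0.0144) and CMT3 (AT1G69770, a DNA methyltransferase gene; 0.99 ± 0.15, 0.0123). The silenced list rose (mean 0.80, median 0.06, adjusted p = 0.00452 and adjusted p = 0.217 with an estimated correlation, 0.00731 by fry), with 3 of 14 members called and 5 adjusted over the list alone.

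Altogether 490 genes were called at day 4, 237 higher and 253 lower, and 121 and 185 of them differed at least 2-fold. Of 234 annotated risers 32 were pseudogenes (13.7%, odds ratio 1.08, 95% interval 0.721 to 1.58, Fisher's exact test, and 1.00, 0.633 to 1.54, below the median level). The share of pseudogenes was thus not detectably different from that of all loci. The dimmest signals lay higher at day 4, with a mean log2 5th percentile of 5.03 against 3.51 at day 1. Of 2703 pseudogenes in the lowest 25% of level, 0 were called higher at day 4 and 239 at day 1. A rise from near background may therefore be missed at day 4. Of 250 annotated genes that were lower, 4 were pseudogenes (odds ratio 0.110, 0.0298 to 0.286, and 0.0708, 0.0144 to 0.212, below the median level). A fall of a locus already near background may be missed too, here and at the other ages. XPL1 (AT3G18000, a phosphoethanolamine methyltransferase gene) rose by 1.36 ± 0.24 (adjusted p = 0.0244). The cytokinin response regulator gene ARR3 (AT1G59940) had a difference of -1.09 ± 0.19 (0.0244), and the iron transporter gene IRT2 (AT4G19680) of -1.62 ± 0.23 (0.0109). The cell cycle list rose (median 0.35, 28 of 30 members positive, none called, 6 adjusted over the list alone, adjusted p = 1.17e-06 and adjusted p = 0.439 with an estimated correlation, 0.0856 by fry). Jasmonate and ethylene defence fell (median -0.78, 2 of 12 members adjusted over the list alone, adjusted p = 0.00310 and adjusted p = 0.606 with an estimated correlation, 0.352 by fry). Storage oil mobilisation and germination fell (median -0.16, 2 of 18 members adjusted over the list alone, adjusted p = 0.0313 and adjusted p = 0.537 with an estimated correlation, 0.183 by fry). That call was lost with cyclic loess (adjusted p = 0.0835), after scaling to reference genes (0.0716), after quantile normalization over all arrays (0.235) and with the groups compared alone (0.0833).

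The sahh1 samples of day 4 differed from each other more than the samples of any other group, with an SD of 0.755 across bright loci against 0.186 to 0.364 in the other 7 groups. Against the wild-type mean, the first and second sahh1 sample had root hair medians of -1.38 and -0.83, heat shock medians of -0.64 and -1.64, cell cycle medians of 0.28 and 0.36, and root marker medians of -0.73 and 0.04. The first sample carried the fall of the root meristem, stele and endodermis list, which without it had a median of 0.04 and was lost (adjusted p = 0.596), as it was without wild-type sample 1 (0.0788). Leaving out 1 sample changed the number called at day 4 more than 1.5-fold for 10 of the 16 samples. It went to 5033 without sahh1 day 4 sample 2, 1699 without sahh1 day 4 sample 1, and 73 without wild-type day 4 sample 2. It went to 85 without wild-type day 4 sample 1, 203 without either wild-type day 1 sample, 236 without either sahh1 day 1 sample and 308 without either sahh1 day 7 sample. Calls were lost without wild-type day 4 sample 2 for CMT3 (0.0736), IRT2 (0.0745) and XPL1 (0.147), and without wild-type day 4 sample 1 for HSP23.6-MITO (0.0823) and HSP17.6II (0.0821). They were lost without either wild-type day 4 sample, in the order of samples 1 and 2, for RHS14 (0.0784 and 0.177), MRH6 (0.0598 and 0.163), SDC (0.0821 and 0.155), FWA (0.0662 and 0.109) and ARR3 (0.114 and 0.143). RHS16 was lost without wild-type sample 1 (0.0559), wild-type sample 2 (0.224), either sahh1 day 1 sample (0.0511) or either wild-type day 1 sample (0.0556). EXPA7 was lost without sahh1 sample 1 (0.0583), wild-type sample 1 (0.0869), wild-type sample 2 (0.241), either sahh1 day 1 sample (0.0539), either wild-type day 1 sample (0.0594) or either wild-type day 10 sample (0.0502). The jasmonate list was lost without sahh1 sample 1 (0.0800), sahh1 sample 2 (0.0816) or wild-type sample 1 (0.102). The silenced list was lost without sahh1 sample 1 (0.102) or 2 (0.0708), and the oil mobilisation list without sahh1 sample 1 (0.261), sahh1 sample 2 (0.0752) or wild-type sample 2 (0.135). With a replicate block MRH6 was lost too (0.0511). TIP2;3, PIP2;4, HSP21 and QQS stayed called without any 1 sample, but were lost with array weights (0.0940, 0.274, 0.517 and 0.177). With the groups compared alone TIP2;3 and PIP2;4 (0.342 each) and HSP21 (0.373) were lost too. The other genes named above for day 4 were lost with array weights (0.383 to 0.823) and with the groups compared alone (0.106 to 0.647). After scaling to the reference genes RHS16 (0.0569), EXPA7 (0.0601) and ARR3 (0.0761) were lost, and ARR3 with 32 arrays and the sample as a random block (0.118). With array weights 17 genes were called (16 higher, 1 lower) and with the day 4 groups alone 11, all higher. After scaling to the reference genes, which moved the median difference of all loci to 0.14, 284 genes were called, 198 higher and 86 lower, and 5366 with 32 arrays in place of samples.

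At day 7, methylation-silenced and other near-silent loci were again among the risers. QQS rose by 3.11 ± 0.37 (adjusted p = 0.00142), FWA by 2.79 ± 0.27 (2.62e-04) and AT4G08680 by 2.66 ± 0.41 (0.0111). The protein-coding loci AT4G29200 (6.27 ± 0.22) and AT2G05915 (6.18 ± 0.25) rose too. FUS3 (AT3G26790), a regulator of seed maturation, rose by 1.34 ± 0.18 (0.00458), and IBM1 fell by 1.29 ± 0.19 (0.00819). RL5 (AT1G19510; -1.59 ± 0.27, 0.0234) and UMAMIT25 (AT1G09380; -1.09 ± 0.19, 0.0275) also fell. In all 191 genes were called, 171 higher and 20 lower, 165 and 11 of them at least 2-fold, and 84 of 171 annotated risers were pseudogenes (49.1%, odds ratio 6.73, 95% interval 4.92 to 9.20, Fisher's exact test). Below the median level the odds ratio was 3.05 (2.22 to 4.19). Of the 20 genes lower at day 7, 9 were pseudogenes too (odds ratio 5.61, 2.05 to 14.9), but below the median level the interval included 1 (3.01, 0.984 to 9.20).

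The silenced list rose at day 7 (mean 0.81, median 0.20, 3 of 14 members, 5 adjusted over the list alone, adjusted p = 2.51e-04 and adjusted p = 0.132 with an estimated correlation, 0.00731 by fry). The root hair list fell as a set with 37 of 42 members negative but none called by limma and 2 adjusted over the list alone (median -0.70, adjusted p = 1.23e-10 and adjusted p = 0.439 with an estimated correlation, 0.322 by fry). The cell cycle list rose, all 30 members positive and none called even adjusted over the list alone (median 0.22, adjusted p = 1.89e-05 and adjusted p = 0.520 with an estimated correlation, 0.289 by fry). Flavonoid and anthocyanin (median 0.39, 2 of 15 members adjusted over the list alone, adjusted p = 0.00342 and adjusted p = 0.537 with an estimated correlation, 0.352 by fry) rose as a set, and so did other SAM-using metabolism (median 0.12, adjusted p = 0.0349 and adjusted p = 0.438 with an estimated correlation, 0.227 by fry). No member of either was called over all genes. The flavonoid call at day 7 was lost without wild-type sample 2 (0.425) or sahh1 sample 1 (0.0571), and the SAM-using list without sahh1 sample 2 (0.150), wild-type sample 1 (0.0688) or wild-type sample 2 (0.144), and with the dimmest 25% of loci left out (0.150). The call of FUS3 was lost without sahh1 sample 1 (0.0605) or wild-type sample 2 (0.0608). That of IBM1 was lost without sahh1 sample 2 (0.0760) or wild-type sample 2 (0.0985) and that of AT4G08680 without sahh1 sample 2 (0.0618) or wild-type sample 1 (0.0786). That of RL5 was lost without sahh1 sample 1 (0.178), sahh1 sample 2 (0.104), wild-type sample 1 (0.116) or wild-type sample 2 (0.0583). That of UMAMIT25 was lost without sahh1 sample 1 (0.0627), sahh1 sample 2 (0.169), wild-type sample 1 (0.131), wild-type sample 2 (0.0649), either wild-type day 1 sample (0.0501) or either sahh1 day 10 sample (0.0515). With a replicate block the calls of IBM1 (0.0576), RL5 (0.0547) and UMAMIT25 (0.0656) were lost, at an age where the first minus second sample differences of the genotypes correlated at 0.740. After quantile normalization over all arrays those of FUS3 (0.365), AT4G08680 (0.0729), RL5 (0.865) and UMAMIT25 (0.108) were lost. With the groups compared alone those of QQS (0.159), FWA (0.156), AT4G08680 (0.545), FUS3 (0.163), IBM1 (0.267), RL5 (0.212) and UMAMIT25 (0.445) were lost. UMAMIT25 was also lost after scaling (0.0629), with an intensity trend and robust prior (0.0715) and with the sample as a random block (0.206). The count was 105 without sahh1 sample 1, 112 without wild-type sample 2, 25 with the day 7 groups alone, 66 after quantile normalization over all arrays and 1025 with 32 arrays in place of samples.

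At day 10, root hair genes were lower in sahh1 by a median of 1.86 on the log2 scale, and 19 of the 42 list members fell (31 adjusted over the list alone). EXT12 (AT4G13390, a cell wall extensin; -2.13 ± 0.22, adjusted p = 3.47e-04), the proline-rich protein genes PRP3 (AT3G62680; -2.29 ± 0.30, 0.00270) and PRP1 (AT1G54970; -2.93 ± 0.46, 0.00896) were among them. So were RHS13 (AT4G02270; -3.05 ± 0.42, 0.00364) and EXPA7 (-1.95 ± 0.28, 0.00444), and RHS13 fell 8.28-fold. The set test gave an adjusted p of 6.70e-42 with the preset correlation (adjusted p = 0.132 with an estimated correlation, 0.00731 by fry). Root meristem, stele and endodermis markers had a median of -0.01 and none was called (adjusted p = 0.635). Risers included QQS (3.31 ± 0.37, 6.22e-04), FWA (2.71 ± 0.27, 2.71e-04), AT4G08680 (3.76 ± 0.41, 5.51e-04) and the pseudogene AT3G32195 (6.93 ± 0.35).

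In all 311 genes were called at day 10, 250 higher and 61 lower, 235 and 55 of them at least 2-fold, and 168 of 249 annotated risers were pseudogenes (67.5%, odds ratio 14.8, 95% interval 11.2 to 19.6, Fisher's exact test). Below the median level the odds ratio was 7.05 (5.32 to 9.42). Of the 61 genes lower at day 10, 5 were pseudogenes (odds ratio 0.610, 0.191 to 1.51). Among loci below the median level, pseudogenes were a smaller share of the lower genes than of the other loci (0.237, 0.0467 to 0.746). SHM4 (AT4G13930, a serine hydroxymethyltransferase gene) rose by 0.67 ± 0.12 (0.0159), HSP17.6II by 1.69 ± 0.23 (0.00332) and the transporter gene ABCG40 (AT1G15520) by 2.07 ± 0.36 (0.0183), while IBM1 fell by 1.08 ± 0.19 (0.0182). The silenced list rose (mean 0.79, median 0.20, 3 of 14 members, 4 higher and 1 lower adjusted over the list alone, adjusted p = 1.24e-04 and adjusted p = 0.132 with an estimated correlation, 0.00731 by fry). Phosphate starvation fell (median -0.86, 5 of 10 members adjusted over the list alone, adjusted p = 1.79e-04 and adjusted p = 0.520 with an estimated correlation, 0.346 by fry). Flavonoid and anthocyanin fell (median -0.47, 1 member adjusted over the list alone, adjusted p = 0.00451 and adjusted p = 0.549 with an estimated correlation, 0.352 by fry), and so did cytokinin response and metabolism (median -0.25, adjusted p = 0.00171 and adjusted p = 0.438 with an estimated correlation, 0.227 by fry). Glucosinolate synthesis (median 0.42, adjusted p = 2.87e-04 and adjusted p = 0.634 with an estimated correlation, 0.496 by fry) rose. Abscisic acid and cold response (median 0.55, adjusted p = 0.0203 and adjusted p = 0.733 with an estimated correlation, 0.632 by fry) rose, and so did nuclear-encoded photosynthesis genes (median 0.09, 40 of 49 positive, adjusted p = 0.00294 and adjusted p = 0.742 with an estimated correlation, 0.580 by fry). In these 6 lists no member was called over all genes, and in the last 3 and the cytokinin list none was called adjusted over the list alone.

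Without sahh1 sample 1 of day 10 the calls of the phosphate (0.0829), flavonoid (0.176), cytokinin (0.0770) and photosynthesis (0.144) lists were lost, and the flavonoid median was 0.01. Without wild-type sample 2 those of the abscisic acid (0.104), photosynthesis (0.117) and flavonoid (0.0503) lists were lost, without sahh1 sample 2 those of the abscisic acid (0.0995) and glucosinolate (0.0908) lists, and without wild-type sample 1 the glucosinolate list (0.168). EXT12, PRP3, QQS, FWA, AT4G08680 and AT3G32195 stayed called without any 1 sample. The call of RHS13 was lost without sahh1 sample 2 (0.0541) or wild-type sample 1 (0.0504), and that of EXPA7 without sahh1 sample 2 (0.0617) or wild-type sample 1 (0.0533). That of PRP1 was lost without sahh1 sample 2 (0.117), wild-type sample 1 (0.0704) or wild-type sample 2 (0.0820) and that of HSP17.6II without wild-type sample 1 (0.0533). That of ABCG40 was lost without sahh1 sample 1 (0.162), sahh1 sample 2 (0.0910) or wild-type sample 1 (0.215). That of SHM4 was lost without sahh1 sample 1 (0.121), sahh1 sample 2 (0.120), wild-type sample 1 (0.166) or wild-type sample 2 (0.0714). That of IBM1 was lost without sahh1 sample 1 (0.156), sahh1 sample 2 (0.0959), wild-type sample 1 (0.216) or wild-type sample 2 (0.0541). With a replicate block the calls of IBM1 (0.0695) and SHM4 (0.104) were lost too. With the groups compared alone those of IBM1 (0.0617), SHM4 (0.153) and ABCG40 (0.0684) were lost, and SHM4 after scaling to the reference genes (0.0731). The number of genes called was 158 without sahh1 sample 2, 162 without wild-type sample 1, 192 without sahh1 sample 1, 184 after quantile normalization over all arrays and 1303 with 32 arrays in place of samples.

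**Figure D3:**
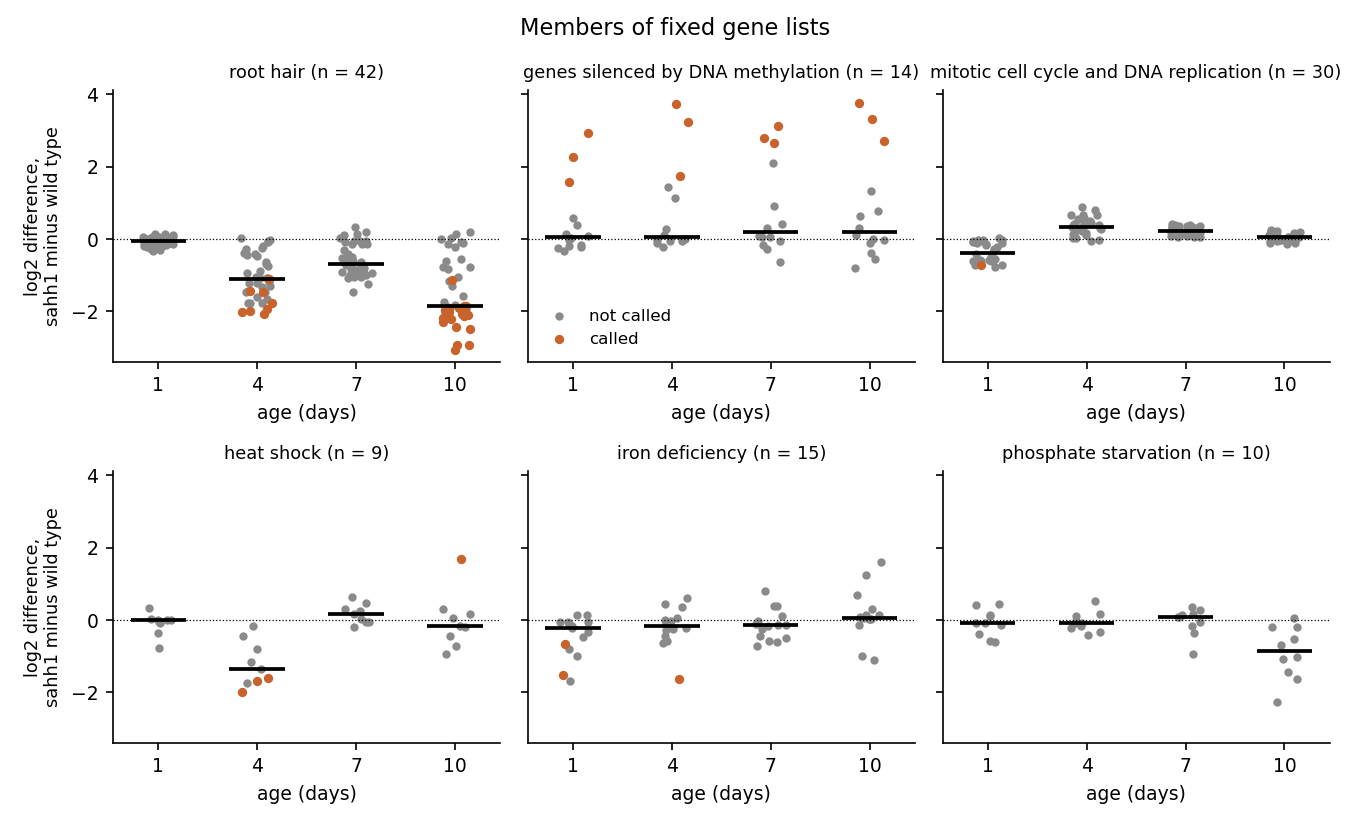
Log2 difference, sahh1 minus wild type, of each measured member (point) of 6 fixed gene lists by age in days, orange where the gene is called, with a black line at the list median. The root hair median goes from -0.05 at day 1 to -1.86 at day 10, and the heat shock median is -1.36 at day 4.

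The 8 remaining lists were called at no age. Over the 4 ages the list medians lay between -0.02 and 0.04 for methyl cycle and methionine (lowest adjusted p 0.237), -0.05 and 0.07 for DNA methylation and silencing machinery (0.187) and -0.12 and 0.09 for auxin response and transport (0.290). They lay between -0.15 and 0.03 for phenylpropanoid and lignin (0.144) and -0.10 and 0.31 for root epidermal patterning (0.0906). They lay between -0.02 and 0.20 for salicylic acid and pathogen defence (0.216), -0.09 and 0.09 for seed storage and maturation (0.111) and -0.08 and 0.04 for the stable reference genes (0.505). The direction of the camera test and the sign of the median differed, with no call, at day 1 for methyl cycle, storage oil mobilisation, salicylic acid and jasmonate. They differed at day 7 for storage oil mobilisation and phosphate starvation (median 0.08, mean -0.04, down by camera). They differed at day 10 for root epidermal patterning, seed storage, phenylpropanoid, heat shock and the reference genes. For auxin at day 7 the mean (0.01) and the median (-0.05) differed. With an estimated correlation no list was called at any age (camera, lowest adjusted p 0.132), and at an unadjusted p under 0.05 there were 3, 3, 1 and 3 lists at days 1, 4, 7 and 10. By fry 1, 3, 1 and 2 lists were called.

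Across the 4 ages, 37 genes rose at every age and 1 fell, where independent lists would share 2.37e-04 and 9.90e-07. The fit gives each gene a single spread for all ages, so the lists are not independent. The shares for independent lists, here and below, are a reference and not a test. The fallen gene was the pseudogene AT4G16870 (-2.02 ± 0.24, -2.18 ± 0.24, -2.27 ± 0.24 and -2.38 ± 0.24 at days 1, 4, 7 and 10). Of the risers 15 were pseudogenes and 3 had a symbol, QQS, NOGC1 and LBD26, of which NOGC1 and LBD26 were chosen after their values were seen. The 10 with the largest mean difference were led by AT3G54730 (5.77 ± 0.30, 5.23 ± 0.30, 5.66 ± 0.30 and 6.16 ± 0.30) and AT2G19850 (5.57 ± 0.28, 5.53 ± 0.28, 5.51 ± 0.28 and 5.99 ± 0.28). The others were AT4G16215, AT1G77960, AT4G29200, AT2G05915, AT2G40955, AT5G45095, AT2G07215 and the pseudogene AT5G27345. QQS differed by 2.28, 3.74, 3.11 and 3.31 and stayed called without any 1 sample at days 4, 7 and 10, but was lost at day 4 with array weights (0.177) and at day 7 with the groups compared alone (0.159). AT4G16870 was lost at day 4 with array weights (0.233) and with the groups compared alone (0.240), which also lost AT3G54730 (0.0759) and AT2G19850 (0.0617) at day 7. Days 7 and 10 shared 135 risers, against 1.41 for independent lists, days 1 and 10 shared 174 (5.40), and days 1 and 7 shared 111 (3.69). Days 1 and 4 shared 53 (5.12), days 4 and 7 shared 51 (1.33) and days 4 and 10 shared 53 (1.95). On the mean of the 4 ages 1058 genes were called, 744 higher and 314 lower, and 3580 with 32 arrays in place of samples. Without sahh1 day 4 sample 2 the number called at every age was 90, and it was 16 with array weights, 6 with the groups compared alone and 132 with 32 arrays in place of samples.

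**Figure D4:**
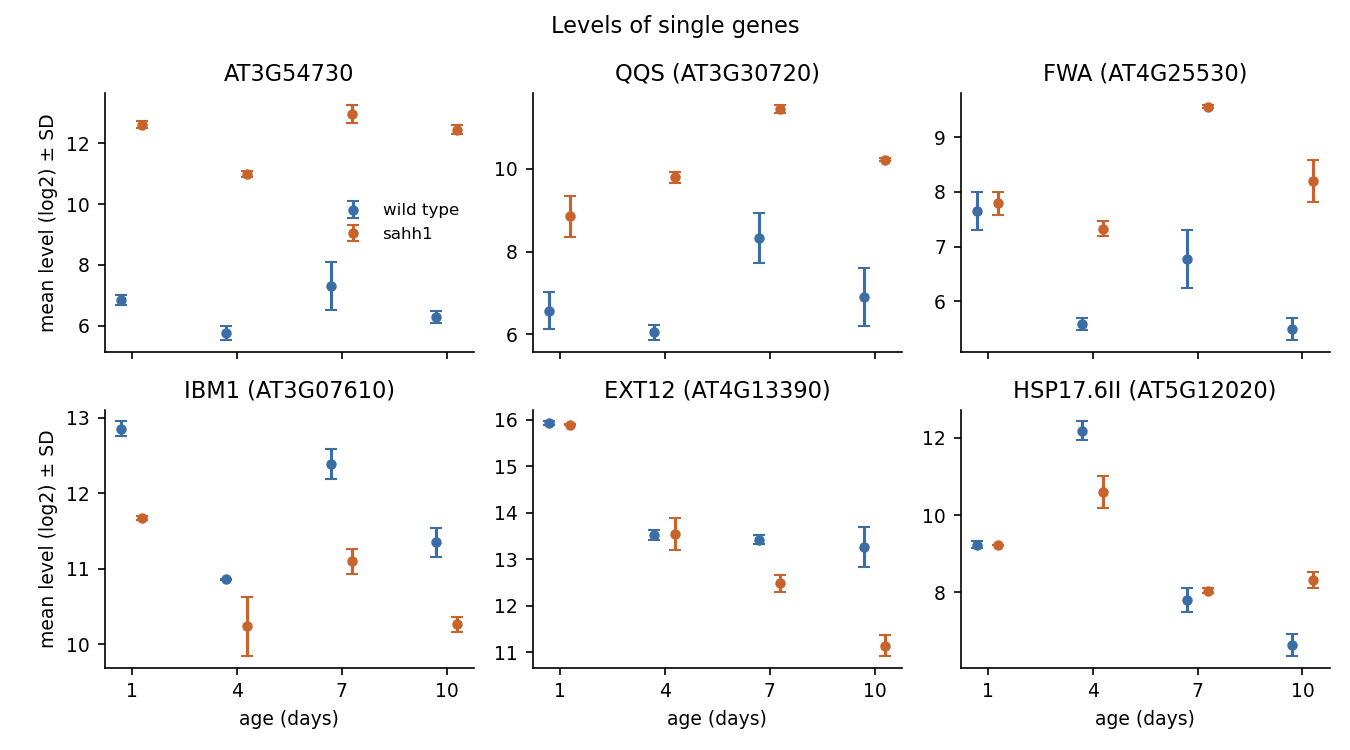
Mean log2 level with the SD of 2 samples for 6 genes by age in days, wild type in blue and sahh1 in orange; levels are as deposited, so genotypes are to be compared within an age. The sahh1 means of AT3G54730 and QQS lie above wild type at all 4 ages, and EXT12 differs by -2.13 at day 10.

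The genotype difference of 187 genes changed with age in an F test over the interaction terms, 107 of them pseudogenes. It fell between days 1 and 4 for 232 genes and rose for 103, of 335 called, among the former 141 pseudogenes. With 32 arrays in place of samples 3350 were called. Dim signals lay higher at day 4 before quantile normalization, so a smaller difference of near-silent loci at that age may reflect the arrays. The 5 genes with the smallest p were AT1G45030, AT1G77960, AT2G12980, AT3G46484 and AT5G33220 (adjusted p = 8.62e-04 each). AT3G46484 fell by 3.05 from day 1 to day 4 in sahh1 and rose by 0.44 ± 0.17 in wild type, and AT5G33220 fell by 2.24 ± 0.15 in sahh1 against -0.22 in wild type. Between days 4 and 7 the difference changed for 9 genes, and for 1470 with 32 arrays in place of samples. Between days 7 and 10 it changed for 0 by limma, with 641 at an unadjusted p under 0.05 and 30 with 32 arrays in place of samples. The F test count moved more than 1.5-fold without sahh1 day 1 sample 1 (66), sahh1 day 1 sample 2 (57), wild-type day 1 sample 1 (61), wild-type day 1 sample 2 (60), sahh1 day 4 sample 1 (2055), sahh1 day 4 sample 2 (1435), sahh1 day 7 sample 1 (90), sahh1 day 7 sample 2 (101), wild-type day 7 sample 1 (120), wild-type day 7 sample 2 (83), sahh1 day 10 sample 1 (96), sahh1 day 10 sample 2 (100), wild-type day 10 sample 1 (115) or wild-type day 10 sample 2 (108). Age is not separable from the distribution each age was normalized to, so these counts rest on quantile normalization over all arrays.

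Between day 1 and day 4, 15739 genes changed in wild type (7333 higher, 8406 lower) and 14932 in sahh1 (6932 and 8000). These differences between ages cannot be told apart from normalization or hybridisation by age. With array weights 17387 genes changed in wild type and 9362 in sahh1, and with the groups compared alone 16057 and 7302. In wild type OSM34 (AT4G11650) rose most, by 9.51 ± 0.22 (8.95 in sahh1), followed by AT3G25190 (9.22) and AT3G06390 (8.98), and scpl44 (AT1G43780; -9.65 ± 0.20), AT1G65090 (-9.61) and the expansin gene EXPA2 (AT5G05290; -9.11) fell most. From day 4 to day 7, 6769 genes changed in wild type (3312 higher, 3457 lower) and 3526 in sahh1 (1739 and 1787). AT1G53540 (-6.76 ± 0.29), the small heat shock protein gene HSP17.6A (AT5G12030; -6.68 ± 0.27) and ABCG40 (-6.25) fell most in wild type, and AT1G67865 (4.997), the defensin gene PDF1.3 (AT2G26010; 4.66) and AT3G05727 (4.61) rose most. From day 7 to day 10, 89 genes changed in wild type (60 higher, 29 lower) and 142 in sahh1 (70 and 72). With a replicate block, and also with the groups compared alone, both counts were 0 (limma, 5030 and 4945 at an unadjusted p under 0.05 with neither), so the genes named for this step rest on the fit without them. CYP71A12 (AT2G30750; 3.42 ± 0.37), CRK15 (AT4G23230; 2.67) and AT4G22470 (2.51) rose most in wild type, and the oil body gene OLEO1 (AT4G25140; -2.41 ± 0.37), AT3G54940 (-2.28) and the glyoxylate cycle gene ICL (AT3G21720; -1.69) fell most. From day 7 to day 10 the count in wild type was moved more than 1.5-fold without either sahh1 day 1 sample (11), either wild-type day 1 sample (16), either sahh1 day 4 sample (1714), either sahh1 day 7 sample (49), wild-type day 7 sample 1 (11), wild-type day 7 sample 2 (0), wild-type day 10 sample 1 (39) or wild-type day 10 sample 2 (0). In sahh1 it was moved without either sahh1 day 1 sample (17), either wild-type day 1 sample (2), either sahh1 day 4 sample (2267), either sahh1 day 7 sample (0), either wild-type day 7 sample (43), sahh1 day 10 sample 1 (0) or sahh1 day 10 sample 2 (1). From day 4 to day 7 it was moved in wild type without either sahh1 day 4 sample (11175), wild-type day 4 sample 1 (4462), wild-type day 4 sample 2 (4475), wild-type day 7 sample 1 (3116) or wild-type day 7 sample 2 (2974). In sahh1 it was moved without sahh1 day 4 sample 1 (11615), sahh1 day 7 sample 1 (871) or sahh1 day 7 sample 2 (1044). After scaling to the reference genes 23100 genes changed from day 1 to 4 in wild type (14787 higher, 8313 lower) and 22057 in sahh1 (15315 and 6742). From day 4 to 7 it was 15667 in wild type (4335 and 11332) and 14510 in sahh1 (2610 and 11900). From day 7 to 10 it was 3021 in wild type (2503 and 518) and 2686 in sahh1 (1885 and 801), so the share rising depends on the scaling, after which the largest median between ages was 0.58. With cyclic loess 44.8% of the genes called from day 7 to day 10 in wild type were higher, against 67.4%. With the values as deposited 25114 genes changed from day 4 to day 7 in wild type (21498 higher, 3616 lower) and 18887 from day 7 to day 10 (81 and 18806). In sahh1 it was 25496 (21560 and 3936) and 18457 (73 and 18384).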

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

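The comparisons below were part of the plan, and all rest on quantile normalization over all arrays, since age is not separable from normalization. The genotype difference varied with age for 187 genes in the F test. It changed between days 1 and 4 for 335 genes and between days 4 and 7 for 9.

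The smallest adjusted p values of the F test were those of AT1G45030, AT1G77960, AT2G12980, AT3G46484 and AT5G33220 (0.000862 each). They were followed, among the named genes, by AT3G32195 (0.00193), AT2G05915 and AT5G27345 (0.00727 each), HSP17.6II (0.00733), ABCG40 (0.0130), AT4G29200 (0.0139), FWA (0.0177), EXT12 (0.0203), HSP21 (0.0233), ARR3 (0.0338), SBT3.3 (0.0344), PIP2;4 (0.0399), AT4G16215 (0.0419), AT1G47400 (0.0481) and AT1G53540 (0.0499995).

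Of 69 tests of lists, 18 were called with the preset correlation and 0 with an estimated one (camera, lowest adjusted p 0.177, and 6 at an unadjusted p under 0.05). Values below are medians over list members of the change of the genotype difference, after quantile normalization. They are not differences between the list medians given above for each age. From day 1 to day 4 the median change was -1.08 for root hair, -1.34 for heat shock and -0.73 for abscisic acid and cold response. It was 0.64 for mitotic cell cycle and DNA replication and 0.68 for flavonoid and anthocyanin. From day 4 to day 7 the median change was 1.69 for heat shock and 0.49 for root hair. It was 0.47 for root meristem, stele and endodermis markers and 0.30 for other SAM-using metabolism. From day 7 to day 10 the median change was -0.95 for root hair, -0.70 for flavonoid and anthocyanin and -0.54 for phosphate starvation. It was -0.31 for cytokinin response, -0.13 for mitotic cell cycle, 0.15 for photosynthesis and 0.31 for glucosinolate synthesis. For abscisic acid and cold response it was 0.56 and for jasmonate and ethylene defence 0.66.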

How the results depend on the processing

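The random block, the crossed block, leaving out each sample, quantile normalization for genotype and deposited values between ages were chosen after the results were seen. Counting each array separately was the count of replicates in the plan. A stricter threshold or a 2-fold minimum can only lower a count. Leaving out a sample does not alter the differences in comparisons that do not use its group. Their counts and calls then move only through the spread pooled over the groups. Otherwise, where a value changed, the cause was not tested. Unless named below, the counts of genes and lists stayed within 1.5-fold and the tests of SAHH1 and SAHH2 on the same side of the threshold.

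With 32 arrays counted separately, 1736, 5366, 1025 and 1303 genes were called at days 1, 4, 7 and 10. There were 132 at all ages, 13231 and 10620 from day 4 to 7 in wild type and sahh1, 5733 and 5765 from day 7 to 10, and 3153 by interaction. On the mean of the ages 3580 were called. The genotype difference changed for 3350 from day 1 to 4, 1470 from day 4 to 7 and 30 from day 7 to 10. SAHH1 at day 10 was called (-0.77, adjusted p = 0.00124). With the sample as a random block the counts were 2048 at day 4, 511 at day 10, 6038 from day 4 to 7 in sahh1, 2317 and 2595 from day 7 to 10, and 691 by interaction. SAHH1 at day 10 was called (-0.77, 0.00996). With array weights they were 1446 at day 1, 17 at day 4, 16 at all ages, 9362 from day 1 to 4 and 39 from day 4 to 7 in sahh1. They were 1531 and 2391 from day 7 to 10, and 356 by interaction. SAHH1 was lost at day 4 (-1.53, 0.103) and called at day 10 (-0.77, 0.0226). With only the groups compared they were 11 at day 4, 25 at day 7, 6 at all ages, 7302 from day 1 to 4 in sahh1. They were 2825 and 0 from day 4 to 7 and 0 and 0 from day 7 to 10. SAHH1 was lost at day 4 (-1.53, 0.542).

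An adjusted p under 0.01 left 56, 107 and 176 genes at days 4, 7 and 10, 2600 and 948 from day 4 to 7 and 0 and 2 from day 7 to 10. SAHH1, with a limma adjusted p of 0.0117 at day 1 and 0.0144 at day 4, is called at neither age at that threshold. A 2-fold minimum left 306 at day 4, 9867 and 9216 from day 1 to 4, 3336 and 1549 from day 4 to 7 and 53 and 88 from day 7 to 10. Without the dimmest loci 424 were called at day 1, 386 and 468 from day 7 to 10 and 116 by interaction. Cyclic loess gave 721 and 446 from day 7 to 10 and 448 by interaction, and an intensity trend with a robust prior 412, 547 and 109. Quantile normalization gave 446, 1337, 66 and 184 at days 1, 4, 7 and 10. Scaling to reference genes gave 284 at day 4, 15667 and 14510 from day 4 to 7, 3021 and 2686 from day 7 to 10 and 365 by interaction. Deposited values between ages gave 25217 and 25214, 25114 and 25496, 18887 and 18457, and 425 by interaction. For the genotype counts the replicate block paired sample numbers across genotypes within an age. It gave 695, 345, 159 and 357 genes at days 1, 4, 7 and 10. Between ages the block paired sample numbers across ages within a genotype, and gave 0 and 0 from day 7 to 10. For the interaction it paired sample numbers over all groups, and gave 132. First minus second sample differences of the genotypes correlated at -0.524, 0.159, 0.740 and -0.122, so sample numbers do not pair across genotypes at every age. Pairing across ages was not examined. Crossing the pairs at days 1 and 10 gave 837 and 414.

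Of the lists, camera with an estimated correlation called 0, 0, 0 and 0 at days 1, 4, 7 and 10 (3, 3, 1 and 3 at an unadjusted p under 0.05), and fry 1, 3, 1 and 2. Of 25 list calls 11 held without any 1 sample and 14 were lost at least once. In 2 of these the median also changed sign: root meristem, stele and endodermis markers at day 4 (0.036 without sahh1 day 4 sample 1, -0.73 without sample 2) and flavonoid and anthocyanin at day 10 (0.015 without sahh1 day 10 sample 1, -0.50 without array 3 of wild type). Of 171 calls of named genes 98 held without any 1 sample, 97 with only the groups compared and 134 with array weights, and none changed sign in any alternative. The calls lost were 28 with quantile normalization, 24 with the replicate block, 17 with scaling, 7 with an intensity trend and robust prior, 5 with the random block, 2 with cyclic loess and 0 with 32 arrays. Without dim loci 6 of 166 were lost. Of the list calls, the groups compared alone lost 2 (silenced genes at day 1, adjusted p = 0.121, and storage oil mobilisation at day 4, 0.0833). Cyclic loess, scaling and quantile normalization each lost storage oil mobilisation at day 4, and leaving out dim loci lost other SAM-using metabolism at day 7. Fry lost 18 and an estimated correlation all 25.

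Leaving out 1 array or 1 sample, where the lone sample of a group is assumed to vary like the other groups, gave 73 to 5033 genes at day 4, 105 to 226 at day 7, and 158 to 413 at day 10. It gave 26 to 90 at all ages, 2974 to 11175 and 871 to 11615 from day 4 to 7. It gave 0 to 1714 and 0 to 2267 from day 7 to 10, 57 to 2055 by interaction and 4 to 8 lists at day 4. The SAHH1 difference lay between -1.33 and -1.20 at day 1, -2.00 and -1.07 at day 4 and -0.87 and -0.67 at day 10. Its call was lost at day 1 without any of the 4 day 1 samples (adjusted p up to 0.108) and at day 4 without either wild-type day 4 sample (up to 0.106), and it was called at day 10 without either sahh1 day 4 sample (0.00673). Leaving out 1 array alone moved no count more than 1.5-fold. Many risers lie near background: risen pseudogenes had a median level of 4.37 in wild type at day 1, under the lower quartile of 4.81, so their fold depends on the background signal.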

Other observations

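The tests of a failed array, of cross-hybridisation, of developmental stage, of root share, of sample identity and of neighbouring loci were chosen after the results were seen. In sahh1 seedlings, loci near background in wild type rose at days 1, 7 and 10, mostly pseudogenes at days 1 and 10, and QQS rose at all 4 ages. The root hair list was lower at days 4, 7 and 10 with the preset correlation, with 8, 0 and 19 of its 42 members called by limma and 30, 2 and 31 adjusted over the list alone. With an estimated correlation it was not called (adjusted p = 0.264, 0.439 and 0.132). At day 10 EXT12 differed by -2.13 and PRP3 by -2.29. SAHH1 was called lower at days 1 and 4.

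The rise of pseudogenes could come from DNA carried over or from higher background on sahh1 arrays, from cross-hybridisation between copies of a repeat, or from loss of silencing. For carried-over DNA and background, the prediction fixed beforehand was an upward shift of dim pseudogenes as a class at day 1. The 2703 pseudogenes in the lowest 25% of level had a median difference of -0.0024, and 239 of them were called higher. The called pseudogenes of all levels had a median of 2.13. In the normalized values the called rises were thus not common to dim pseudogenes as a class. Normalization within an age would remove a rise that dim loci share, so this test cannot decide the prediction. A shared rise beside the called ones, or one that differs between loci, stays open. Cross-hybridisation cannot be told apart from the rest: 106 protein-coding loci also rose at day 1, but the probe sequences are not known. Lost silencing stays open too, as 3 of 14 genes silenced by DNA methylation rose at each age but DNA methylation was not measured.

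The first sahh1 sample of day 4 lies apart from its partner, which could reflect a failed array, a wild-type sample, or a later stage. Its 2 arrays differed with an SD of 0.218, less than the 0.448 of the other pair, so a failure of either array alone does not account for it. That test does not cover the arrays of the partner, whose 0.448 was the largest SD within any pair. It also does not cover a fault of the sample that both arrays would share. Its SAHH1 level was 12.98 against a wild-type mean of 14.98 (SD 0.0635), so a wild-type sample does not account for it. Its difference from its partner correlated at 0.465 with the wild-type change from day 4 to day 7, and root hair genes were lower in it (by a median of -0.62, against -2.11 for that change). The heat shock list went the other way (0.24 against -2.25), so a later stage cannot be told apart from growth or handling that moves some of the same genes. The wild-type change between ages is itself not separable from normalization by age.

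Root hair genes had a shortfall at day 10 (median -1.86, bootstrap 95% interval -1.99 to -1.15). It could come from less root in the seedling, from younger seedlings, or from fewer or shorter hairs. The intervals given here come from resampling list members and not samples. They show the spread between genes and not that between the 2 samples per group. Less root would lower the other root markers alike, but the root hair median lay below theirs by -1.85 (-2.00 to -1.09). In wild type the list changed by 0.0331 (-0.123 to 0.168) from day 7 to day 10, too little for a delay of 3 days to give the shortfall, if quantile normalization makes these ages comparable. The list fell with the preset correlation and by fry but not with an estimated correlation (adjusted p = 0.132), and hairs were not measured.

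Adjacent loci were both higher, on the mean of the ages, in 118 pairs, against a median of 48 (95% range 36 to 61) when the calls were reassigned within biotype and chromosome. The p of 1e-04 is the smallest that 10000 reassignments can give. Copies next to each other that share sequence would also give such pairs.

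Among 100 assignments of the genotype labels within ages, the real one included, of 648 possible ones, 1 called as many genes on the mean of the ages as the real labels, namely the real one itself with 1058. The highest of the others called 537.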
